A study of Mus musculus with 12 samples.

How the data were processed

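RNA was measured in growing mouse oocytes at day 14, wild type (WT) or lacking Mtr4 (Mtr4-null), after nucleus and cytoplasm had been separated by micromanipulation. Per the labels' protocols, total RNA from 10 nuclei or 10 cytoplasms per sample was extracted with TRIzol, depleted of ribosomal RNA and sequenced as 150 bp read pairs. The deposited table holds FPKM (fragment counts scaled by transcript length and by the fragments mapped in each library), which per the submitters' processing notes came from TopHat2 2.1.1 and Cufflinks 2.2.1 with the mouse genome build mm9. The role of each tool, the annotation and the use of strand are not given in the sources used here. FPKM is a share of the mapped fragments of a library, so an RNA class that takes more of a library lowers the values of all other genes in it.

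The table has 23235 gene entries for 12 libraries, in 4 groups of 3, and each column was matched to its sample by the sample's title. The design text speaks of duplicates, while 3 libraries per group are labelled. Nothing in the labels says that the 3 libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be technical. No 2 libraries held identical values. Of the entries, 3722 were at 0 in every library, and 12 names look like dates, as spreadsheet programs write some gene symbols, and were kept as given. Genes that every cell uses were at 0 in single libraries, so a 0 is given as listed at 0, with the value of each library and no fold change against a group that is at 0 throughout. Differences of genotype effects that rest on such a group are said not to be folds.

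Read numbers were not used here, and FPKM from Cufflinks gave no whole reads, so absolute depth and detection limits are unknown. Relative depth was estimated from the smallest values (below 0.3 FPKM) of genes shared between libraries, against WT cytoplasm replicate 1. It was 0.174, 0.143 and 0.166 in the WT nuclei, 0.147, 0.129 and 0.398 in the nuclei labelled Mtr4-null, 1.56 and 1.41 in WT cytoplasm replicates 2 and 3, and 1.12, 0.520 and 0.669 in the Mtr4-null cytoplasms. Through WT cytoplasm replicate 2 the value for the library labelled Mtr4-null nucleus replicate 1 was 0.440 in place of 0.147, so it is uncertain; the others did not move. Nuclear values, and above all low ones, are thus less precise than cytoplasmic values.

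Genes with at least 1 FPKM in at least 3 of the 12 libraries were tested (13157). Values were log2(FPKM + 1), so the fold change of a gene of low level is understated. A single limma fit (limma 3.58.1, R 4.3.3) had a mean for each of the 4 groups and moderated variances with a trend on expression, and its 5 comparisons were Mtr4-null against WT in the nucleus and in the cytoplasm, nucleus against cytoplasm in each genotype, and the difference of the genotype effects between compartments (the interaction). P-values are two-sided and adjusted by Benjamini and Hochberg within each comparison, and calls are at an adjusted p below 0.05. Values after ± are standard errors for log2 fold changes and SDs (n = 3) for FPKM. The replicate numbers are not said to pair samples, so no block was used.

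The 33 gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, then with an estimated correlation, and with fry. The lists were nuclear exosome subunits, MTR4 partner complexes, snoRNA host genes, nuclear lncRNAs, small structured noncoding RNAs, replication-dependent histones, zona pellucida and oocyte-secreted factors, maternal-effect genes, oocyte transcription factors, meiotic arrest and maturation, meiotic prophase and recombination, ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, mitochondrially encoded genes, PI3K-mTOR growth signalling, mRNA export and TREX, splicing factors, cytoplasmic RNA decay, chromatin modifiers, 2-cell-stage genes, p53 targets, interferon-stimulated genes, integrated stress response, immediate early genes, proteasome, nuclear pore and lamina, antisense and opposite-strand transcripts, Gm and Rik genes (predicted genes without a given name), small RNA precursors, and markers of granulosa cells, of theca and stroma, and of blood and endothelium. Some genes stand in more than 1 list.

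The groups, the tests, the lists, the alternatives and the rule for naming genes were set before the data were examined. Per comparison the rule takes, among called genes whose 3 against 3 libraries do not overlap (10% of unchanged genes would by chance) and whose higher group averages at least 5 FPKM, the 10 largest rises and 10 largest falls with a given name, and the 2 largest rises and falls among Gm and Rik genes. Without these conditions on separation and level it takes up to 4 called members of each list that was called or had at least 3 called members, the 2 most abundant members of other lists described, and Skiv2l2 (the symbol of Mtr4 in this table), Gdf9, Bmp15, Zp1, Zp2, Zp3, Kit, Nobox, Figla, Malat1, Neat1, Xist and Gas5. Neat1 and Xist were not among the genes tested. For the interaction the separation of libraries is not asked. Genes named outside the rule are said to be so. A gene that the rule takes in the nucleus is not reported here.

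Simulated data with the spread of each group held 13157 genes, of which 200 were changed. The 200 were drawn from genes whose mean log2 value was at least that of 5 FPKM. The shares recovered therefore do not cover genes of lower level. The procedure was tested on these data. At a log2 change of 2 it recovered 67% of changed genes in the nucleus between genotypes, 67% in the cytoplasm, 65% between compartments in WT and 73% in Mtr4-null, and 16% for the interaction; at a change of 1 the shares were 25%, 5%, 6%, 17% and 1%. False calls were 287, 3, 8, 116 and 6 genes in the same order, because the spread of the nuclei labelled Mtr4-null exceeds the shared estimate. A list shifted by 0.5 was found in each comparison. Among the other tested lists, 3 were called in the cytoplasm and 0 elsewhere by camera. Genes were simulated independently of each other, while real lists correlate (estimated at 0.46 for ribosomal proteins). These list calls therefore do not show how often camera calls real lists falsely. The median SD of log2 values was 0.42 in WT nuclei, 0.13 in WT cytoplasm, 0.75 in nuclei labelled Mtr4-null and 0.23 in Mtr4-null cytoplasm.

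The alternatives were a pseudocount of 0.1, no filter, a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, a replicate block, fits of only the 2 groups compared, variances without a trend, limma's library weights, a fold threshold, and leaving out each library in turn. Fits without the doubtful nucleus libraries, and composition without each library in turn, were added after the data were seen. Composition of libraries was compared with exact two-sided permutation tests of 3 against 3. Neighbouring genes were taken from the GRCm38.p6 annotation, which is another build than the table's, so no coordinates are given. Genes in families of near-identical copies (histones, olfactory and vomeronasal receptors, Speer, Dcpp, Rnaset2 and the major histocompatibility genes) and small RNA genes shorter than the sequenced fragments carry uncertain values, as do genes that overlap others.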

Results

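The data describe where RNA lay in growing oocytes of day-14 mice with and without MTR4, the helicase that feeds RNA to the nuclear exosome, the complex that trims and degrades RNA in the nucleus. Nuclei and cytoplasms of WT and Mtr4-null oocytes were sequenced as total RNA without ribosomal RNA, in 3 libraries per group, 12 in all. The question set by the design is which RNAs change in each compartment when MTR4 is missing, and how RNAs are divided between the compartments.

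Skiv2l2, the gene for MTR4, was at 21.1, 19.4 and 20.2 FPKM in the WT cytoplasms and at 1.04, 0.315 and 0.700 FPKM in the Mtr4-null cytoplasms. The log2 fold change was -3.68 ± 0.57 (limma adjusted p = 0.0048), with every Mtr4-null library below every WT library. The WT nuclei held 6.06, 2.45 and 5.37 FPKM. Of the nuclei labelled Mtr4-null, replicates 2 and 3 held 0.182 and 1.12 FPKM, while the library labelled Mtr4-null nucleus replicate 1 held 7.98 FPKM, above all 3 WT nuclei. With all 3 libraries the nuclear log2 fold change was -0.93 ± 0.57 (adjusted p = 0.42), and without the library labelled Mtr4-null nucleus replicate 1 it was -1.76 (adjusted p = 0.015, and 0.26 in a fit of the nuclei alone). The label of this library is therefore in doubt, and every direction given for nuclei labelled Mtr4-null includes it unless stated.

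**Figure D1:**
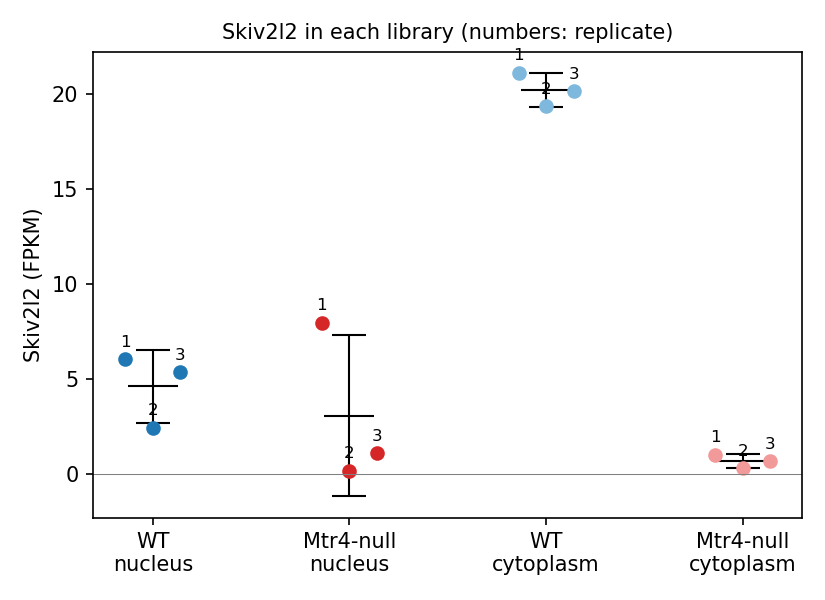
Skiv2l2 in each library. The vertical axis is FPKM, points are libraries with their replicate number, and bars are group means with SD (n = 3). The library labelled Mtr4-null nucleus replicate 1 lies at 7.98 FPKM, above the WT nuclei, and the Mtr4-null cytoplasms lie at 1.04 FPKM or less against at least 19.4 in WT.

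The compartments had distinct makeups. Scarna2, a small Cajal body RNA, took 58.0 to 81.7% of the summed FPKM of the nuclei. The 100 most abundant genes held 93.0 ± 0.66% of the sum in WT nuclei and 87.8 ± 10.1% in nuclei labelled Mtr4-null (n = 3 each; exact permutation p = 0.80), against 26.3 ± 2.75% and 28.5 ± 6.64% in the WT and Mtr4-null cytoplasms (exact permutation p = 0.70). At least 1 FPKM was reached by 12238 ± 675 genes in WT nuclei and 11192 ± 877 in nuclei labelled Mtr4-null (exact permutation p = 0.20), and by 11054 ± 106 and 11380 ± 163 genes in the WT and Mtr4-null cytoplasms (exact permutation p = 0.10, the smallest that 3 against 3 can give). The first principal component (59.1% of the variance) separated compartments, except that the library labelled Mtr4-null nucleus replicate 3 lay at 15.8, between the other nuclei (-106 to -74.2) and the cytoplasms (63.4 to 77.9). The Spearman correlation across genes of that library was 0.93 with Mtr4-null cytoplasm replicate 1 and 0.79 to 0.81 with the WT nuclei. The library labelled Mtr4-null nucleus replicate 1 correlated at 0.86 with each WT nucleus and at 0.76 and 0.84 with the other nuclei of its label. The values are across genes, which are not independent replicates.

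**Figure D2:**
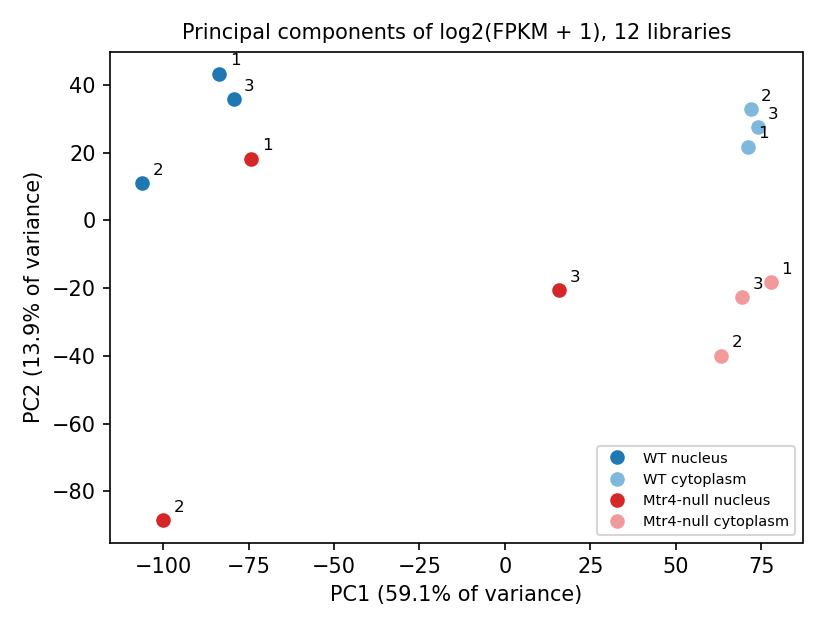
Principal components of log2(FPKM + 1) over the tested genes. The axes are components 1 and 2 with their share of the variance, and each point is a library with its replicate number. The nuclei labelled Mtr4-null are spread out, with replicate 1 near the WT nuclei and replicate 3 at 15.8 on component 1.

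In Mtr4-null cytoplasm some transcripts that WT cytoplasm barely held were abundant. Mt1, which encodes the metal-binding protein metallothionein 1, was listed at 0, 0.138 and 0.152 FPKM in WT and at 222, 316 and 246 FPKM in Mtr4-null cytoplasm (log2 fold change 7.89 ± 1.34, adjusted p = 0.0078). The zinc transporter gene Slc30a2 rose from 1.43 ± 0.716 to 21.0 ± 3.84 FPKM (log2 3.21 ± 0.62), and Stk36, a kinase of motile cilia, from 5.30 ± 0.427 to 85.8 ± 6.90 FPKM (log2 3.78 ± 0.66). Lypd3, a gene for a membrane-anchored surface protein, rose from 1.19 ± 0.346 to 36.7 ± 6.83 FPKM, Prr15l by 4.08 ± 0.67, the pseudogene Cyp2c53-ps by 3.55 ± 0.58, and Ier2, an immediate early gene, by 3.06 ± 0.59 on the log2 scale. Defb8, of the beta-defensins, was listed at 0 in all 3 WT cytoplasms and at 14.8, 19.2 and 13.6 FPKM in Mtr4-null. Rnaset2b, an RNase T2 gene, was likewise at 0 in WT and at 11.7, 25.1 and 11.3 FPKM in Mtr4-null (adjusted p = 0.0046 and 0.0053). Rn45s, the precursor of ribosomal RNA, stood at 1879.9, 805 and 332 FPKM in WT and 2211, 20429 and 9796 FPKM in Mtr4-null cytoplasm (log2 3.26 ± 0.67), although ribosomal RNA had been depleted from the libraries. Prr15l was listed at 0, 0.0403 and 0 FPKM in the WT cytoplasms. Among unnamed genes, Gm13103, at 0.0446, 0.0286 and 0 FPKM in WT, stood at 75.5, 65.0 and 54.7 FPKM in Mtr4-null, 4930470H14Rik rose by 4.05 ± 0.39 and E030030I06Rik by 3.64 ± 0.43. WT nuclei held both of the last, 4930470H14Rik at 1149, 674 and 1122 FPKM and E030030I06Rik at 33.4, 19.3 and 27.1 FPKM.

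Other cytoplasmic transcripts nearly vanished. Pnpla3, which encodes a lipid droplet hydrolase, fell from 103 ± 2.79 to 1.54 ± 0.279 FPKM (log2 -5.36 ± 0.44, adjusted p = 2.4e-05). Pxdn, for the matrix peroxidase peroxidasin, fell from 41.4 ± 3.88 to 0.277 ± 0.109 FPKM (log2 -5.05 ± 0.79), and Bcat2, the mitochondrial aminotransferase of branched-chain amino acids, from 86.4 ± 6.60 to 2.61 ± 0.706 FPKM (log2 -4.62 ± 0.89). Slc26a5, the gene of the motor protein prestin, fell by 4.48 ± 0.57, the kinase gene Dclk1 fell by 4.05 ± 0.61, and the salivary protein gene Dcpp1 fell by 4.26 ± 0.62 on the log2 scale. Its neighbour in the same family, Dcpp2, was at 16.8, 19.4 and 14.2 FPKM in WT and listed at 0 in all 3 Mtr4-null cytoplasms. In Mtr4-null cytoplasm Dclk1 was listed at 0.0576, 0 and 0.0429, Dcpp1 at 0, 0.339 and 0, and Hist2h2ac at 2.43, 0 and 3.50 FPKM. A430084P05Rik fell by 3.96 ± 0.55 and D430041D05Rik fell by 2.74 ± 0.61. Of 49 replication-dependent histone genes, 3 fell and 0 rose (6 and 1 adjusted over the list alone), while a fit of the 6 cytoplasm libraries alone had 7 that fell and 7 that rose. The 3 were Hist2h2bb, from 1749 ± 537 to 57.2 ± 12.7 FPKM (log2 -4.89 ± 0.53), Hist2h3b (log2 -4.69 ± 0.76) and Hist2h2ac (log2 -4.63 ± 0.74), all named for the same gene cluster. The median of the list was 0.29 while its mean was -0.05, and the camera test did not call it (adjusted p = 0.85).

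**Figure D3:**
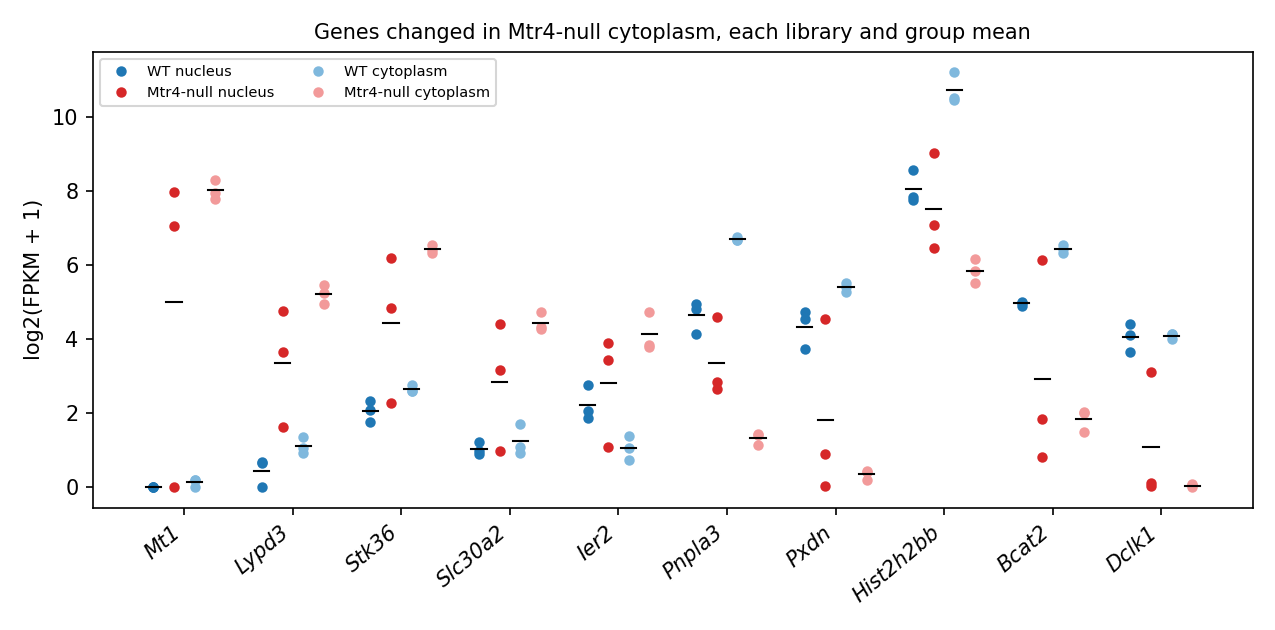
Genes with large changes in Mtr4-null cytoplasm. The vertical axis is log2(FPKM + 1), points are the 3 libraries of each group and lines are group means. Pnpla3 lies at 1.73 FPKM or less in the Mtr4-null cytoplasms, while Mt1, listed at 0 in the library labelled Mtr4-null nucleus replicate 1, is at 133 and 251 FPKM in the other nuclei of that label.

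In all, 248 genes were called between the cytoplasms, 154 higher and 94 lower in Mtr4-null. None of the 32 tested lists was called by camera (5 lists at an unadjusted p below 0.05; smallest adjusted p = 0.13), by the estimated correlation (0 lists; smallest adjusted p = 0.98) or by fry (0 lists). Gm and Rik genes counted 49 that rose and 11 that fell among 1644 (93 and 24 adjusted over the list alone; camera adjusted p = 0.13). Transcripts of the growing oocyte stayed without a call, with Gdf9 at 0.01 ± 0.46, Zp1 at 0.20 ± 0.54, Zp2 at 0.68 ± 0.56, Zp3 at 0.47 ± 0.50, Bmp15 at -0.55 ± 0.53, Kit at -0.04 ± 0.48, Nobox at -0.71 ± 0.36 and Figla at 0.66 ± 0.34 on the log2 scale. Under quantile normalization the values of Gdf9 (-0.94) and Kit (0.12) had the opposite sign, without a call. Of 13 nuclear exosome subunits 0 rose and 0 fell, and Exosc4 was at 0.02 ± 0.45. Among 82 small RNA precursors 3 rose and 1 fell (4 and 1 adjusted over the list alone). Snora47 was at 3.88 ± 0.48, and Snora17 at 24.7, 0 and 0 FPKM in WT and 88.0, 262 and 73.9 FPKM in Mtr4-null. Mir32 was listed at 0 in WT and at 233, 2516 and 1172 FPKM in Mtr4-null, and Mir365-2 at 24.3, 15.6 and 34.4 FPKM in WT and listed at 0 in all 3 libraries of Mtr4-null.

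The spread of the cytoplasms was smaller than the shared estimate. A fit of the 6 cytoplasm libraries alone called 3050 genes, 1754 higher and 1296 lower, which included 247 of the 248. In simulated data the fit of the cytoplasms alone recovered 59% and 80% of genes changed by 1 on the log2 scale, in 2 runs. The fit of 4 groups recovered 7% and 5% there. At a change of 2 the shares were 91% and 98%, against 68% and 65%. False calls were 21 and 14, against 0 and 0. A call lost in a fit of 4 groups thus need not be an unchanged gene. The call that the fit of the cytoplasms alone ended was that of Rn45s (adjusted p = 0.062). Of the oocyte genes named above, that fit called Figla (0.66, adjusted p = 0.020) and Nobox (-0.71, adjusted p = 0.048). In that fit maternal-effect genes (0 of 37 rose, 10 fell; adjusted p = 0.034), genes of meiotic arrest and maturation (2 of 34 rose, 10 fell; adjusted p = 0.032) and ribosomal proteins (0 of 85 rose, 7 fell; adjusted p = 0.040) were called lower by camera. With an estimated correlation the adjusted p was 0.96 for each. Granulosa cell markers had 0 of 13 that rose and 5 that fell there (camera adjusted p = 0.15), and the summed FPKM of 28 of these markers was 266, 296 and 301 in WT and 244, 187 and 231 in Mtr4-null cytoplasm. Nuclear exosome subunits had 2 of 13 that rose and 1 that fell (adjusted p = 0.81), and MTR4 partner complexes 4 of 16 that rose and 0 that fell (adjusted p = 0.91). The count of 248 fell to 84, 56 and 57 without WT cytoplasm replicates 1, 2 and 3, and to 79, 79 and 73 without Mtr4-null cytoplasm replicates 1, 2 and 3. It was 523, 493 and 614 without the nuclei labelled Mtr4-null replicates 1, 2 and 3, which enter only through the shared spread. Of the 30 named calls, Bcat2, D430041D05Rik and Mir32 were lost on leaving out any of the 6 cytoplasm libraries (highest adjusted p = 0.079, 0.15 and 0.12). Slc30a2 and Ier2 were lost without 5 of the 6, Rn45s without 4 and Snora17 without 3 (highest adjusted p = 0.085, 0.091, 0.11 and 0.075). Median-of-ratios scaling ended the calls of Prr15l, Rnaset2b, Ier2, Bcat2, D430041D05Rik and Mir32. Quantile normalization ended these and those of Cyp2c53-ps, Rn45s, Slc30a2, Hist2h3b and Hist2h2ac. Without the filter, Mt1, Stk36, Rn45s, Slc30a2, Ier2, Bcat2, D430041D05Rik, Mir32, Snora17 and Snora47 lost the call, and with a pseudocount of 0.1 Cyp2c53-ps and Hist2h2ac did.

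In the nucleus, several noncoding RNAs were lower in libraries labelled Mtr4-null than in WT, with the library labelled Mtr4-null nucleus replicate 1 included. Ipw, an imprinted noncoding RNA, fell from 121 ± 28.1 to 19.7 ± 24.2 FPKM (log2 -3.20 ± 0.64, adjusted p = 0.019), with 47.7 FPKM in the library labelled Mtr4-null nucleus replicate 1 and 5.32 and 6.20 in the others. Airn, the noncoding RNA of the Igf2r imprinted region, fell from 26.7 ± 10.3 to 7.58 ± 6.08 FPKM (log2 -1.85 ± 0.45) and Peg13, another imprinted noncoding RNA, from 2.40, 1.57 and 2.52 to 0.329, 0 and 0 FPKM (log2 -1.51 ± 0.25). Of 11 nuclear lncRNAs 2 fell and 0 rose (5 and 0 adjusted over the list alone), with a list median of -1.08 (camera adjusted p = 0.00022). Of 16 snoRNA host genes, Taf1d alone fell (log2 -1.62 ± 0.37) and 0 rose. Adjusted over the list alone 3 fell and 0 rose, with a list median of -0.72 (camera adjusted p = 0.0056). Both lists had an adjusted p of 0.49 with an estimated correlation, and both lost the call without replicates 1 and 3 of the nuclei labelled Mtr4-null. Genes higher in WT nuclei, chosen without a WT nucleus library at a time, were lower too. Their median difference from the other WT nuclei was -0.87 to -0.62, -1.33 to -1.09 and -0.98 to -0.80 in replicates 1, 2 and 3 of that label, against 0.17, -0.66 and 0.25 in the WT nuclei left out. Malat1, an abundant nuclear noncoding RNA, stood at 449 ± 170.4 and 184 ± 83.0 FPKM (log2 -1.29 ± 0.47, adjusted p = 0.16), and Gas5 at -0.86 ± 0.28 (adjusted p = 0.12), both without a call.

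Among other falls in the nucleus were Dclk1 (log2 -2.97 ± 0.61), Cav1, for the membrane protein caveolin 1 (-2.44 ± 0.42), and the calcium-binding S100a11 (-2.66 ± 0.59). Further falls were Selm (-2.47 ± 0.50), Cldn27 (-2.48 ± 0.31), Olfr1423 (-2.48 ± 0.51) and the multicopy Speer8-ps1 (-3.16 ± 0.32) and Speer4a (-2.43 ± 0.49). Gm15292 fell by 3.43 ± 0.72, and 1600014K23Rik was at 11.2, 11.2 and 4.83 FPKM in WT and listed at 0 in all 3 libraries labelled Mtr4-null. Snora43 was at 174, 141 and 426 FPKM in WT nuclei and at 0 in the same 3 libraries (adjusted p = 3.7e-08). Cav1, S100a11, Selm, Cldn27, Olfr1423 and Gm15292 were listed at 0 in at least 1 library labelled Mtr4-null (Cav1 at 2.08, 0 and 0, S100a11 at 0, 0 and 1.22 FPKM). Among genes with a given name other than small RNA precursors, the rises were led by Dpm3, a subunit of dolichol-phosphate mannose synthase (log2 3.17 ± 0.74), Gin1 (3.13 ± 0.60), Arl8a, a lysosomal GTPase (2.93 ± 0.47, from 0.401 ± 0.163 to 11.9 ± 8.36 FPKM), Lypd3 (2.89 ± 0.58), and Tusc1 (2.59 ± 0.49). They went on with Hp, for haptoglobin (2.44 ± 0.39), Hist1h2bh (2.24 ± 0.48), Fam58b (2.21 ± 0.41) and Scand1 (2.13 ± 0.41). Nme1, a nucleoside diphosphate kinase gene, was listed at 0 in all 3 WT nuclei and at 3.36, 9.30 and 5.67 FPKM in those labelled Mtr4-null. Dpm3 was listed at 14.6, 0 and 4.39, Gin1 at 0.455, 0 and 0 and Lypd3 at 0.587, 0 and 0.616 FPKM in the WT nuclei, and Hp, Hist1h2bh and both genes named next had a 0 there too. 1110006O24Rik rose by 4.08 ± 0.67 and 1700021F07Rik by 2.62 ± 0.50. The small RNA precursors counted 2 that rose and 3 that fell among 82 (3 and 6 adjusted over the list alone, camera adjusted p = 0.065). Without the library labelled Mtr4-null nucleus replicate 1, camera at the preset correlation called this list lower (adjusted p = 0.043). It then also called immediate early genes higher and theca and stroma markers lower (camera adjusted p = 0.043 for each). Mir1893 and Mir5122 rose, at less than 0.3 FPKM in each WT nucleus and at 901, 5488 and 744 and 2042, 1941 and 731 FPKM in those labelled Mtr4-null. Mir680-1 was at 785, 191 and 1153 FPKM in WT nuclei and listed at 0 in the others.

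Lists of mRNAs were higher in the nuclei labelled Mtr4-null by camera. Oxidative phosphorylation had a median of 0.52 (3 of 83 rose, 0 fell, 9 and 0 adjusted over the list alone; adjusted p = 1.8e-06), with Sdhb (1.69 ± 0.42) and Atp5j2 (1.48 ± 0.33) among the rises and Atp5s listed at 0 in WT. The proteasome had a median of 0.55 (1 of 44 rose, 1 adjusted over the list alone, adjusted p = 0.00073), with Psmb5 at 1.86 ± 0.45. For ribosomal proteins the median was 0.26 (1 of 85 rose, 1 adjusted over the list alone, adjusted p = 0.015), with Rpl36al at 1.88 ± 0.35. Replication-dependent histones had a median of 0.55 (2 of 49 rose and 1 fell, 3 and 1 adjusted over the list alone, adjusted p = 0.016). Among histones Hist1h3f rose by 1.67 ± 0.39 and Hist1h1t fell by 1.95 ± 0.38. Gm and Rik genes were called lower (13 of 1644 rose and 61 fell, 31 and 1.2e+02 adjusted over the list alone; adjusted p = 0.0093). The adjusted p was 0.96 for each of these 5 lists with an estimated correlation, fry called 0 lists, and under quantile normalization histones, ribosomal proteins, the proteasome and Gm and Rik genes were no longer called. Without the library labelled Mtr4-null nucleus replicate 3, ribosomal proteins and Gm and Rik genes lost the call and the other 3 kept it. Without replicates 1 and 3 only oxidative phosphorylation and histones kept it. Histones lost the call without replicate 2, without WT nucleus replicate 3 and with library weights, and ribosomal proteins with the last 2. Over the 5926 genes higher in WT cytoplasm, the median difference from the WT nuclei was 1.08 on the log2 scale in replicate 3, against 0.21 and -0.30 in replicates 1 and 2. Among oocyte genes, Gdf9 (0.64 ± 0.46), Zp1 (-0.09 ± 0.54), Zp2 (-0.10 ± 0.56), Zp3 (0.26 ± 0.50), Bmp15 (-0.22 ± 0.53), Kit (-0.21 ± 0.48), Nobox (0.46 ± 0.36) and Figla (0.44 ± 0.34) had no call, and Zp1 (0.10) and Zp2 (0.21) changed sign under quantile normalization.

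In all, 298 genes were called between the nuclei, 68 higher and 230 lower in those labelled Mtr4-null. Simulated data with the spread of these groups gave 287, 227 and 213 false calls in 3 runs, so the count is not a number of changed genes. A fit of the 6 nucleus libraries alone called 5 genes, Snora43, 1600014K23Rik, Mir1893, Mir5122 and Mir680-1. In simulated data this fit recovered 0% of genes changed by 1 or 2 on the log2 scale, so the other 33 of the 38 named calls are not judged by it, and their fold changes are the same there. Apart from such fits, Snora43, 1600014K23Rik, Cldn27, Fam58b, Hp, Peg13 and Speer8-ps1 kept the call in every alternative that tested them. Those alternatives also take in the smaller spread of the cytoplasms, so a kept call can still be false. The highest adjusted p on leaving out a library was 0.025 for Arl8a, 0.017 for Nme1, 0.069 for Ipw, 0.17 for Airn, 0.13 for Taf1d, 0.082 for Dclk1 and 0.084 for Dpm3. Of the 38 named calls 27 were lost with library weights, 18 with a pseudocount of 0.1 and 23 without WT nucleus replicate 1. The last included Lypd3, Tusc1, Hist1h2bh, Scand1, S100a11, Olfr1423, Selm, Speer4a and Gm15292. Of the list members, Sdhb lost the call without 11 of the 12 libraries in turn, Hist1h3f without 10, Psmb5 without 9 and Atp5j2 without 6 (highest adjusted p = 0.11, 0.11, 0.17 and 0.094). The count was 125, 444 and 203 without WT nucleus replicates 1, 2 and 3, and 1347 (603 higher, 744 lower), 459 (269 higher, 190 lower) and 391 (58 higher, 333 lower) without the nuclei labelled Mtr4-null replicates 1, 2 and 3. Simulated data without the library labelled Mtr4-null nucleus replicate 1 gave 794 and 958 false calls, against the 1347. The spread simulated was that of all 3 libraries of the label. False calls and recovery in these simulated data thus do not describe real fits without this library. The fit of the nuclei alone without this library called 50 genes, also with 0% recovered in simulated data, and 3966 genes were called without replicates 1 and 3, when the last library of its group is assumed to vary like the other groups. Leaving out single cytoplasm libraries, which enter through the shared spread, gave 163 to 181 calls. Quantile normalization called 1140 genes with 498 higher and 642 lower (43.7% higher, against 22.8%), and the filter at 5 FPKM called 26, 19 higher and 7 lower. The median over all genes was 0.04, and -0.11 after median-of-ratios scaling.

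Between the compartments of WT oocytes, small nuclear RNAs and long noncoding RNAs lay on the nuclear side. Malat1 was at 449 ± 170.4 FPKM in nuclei and 1.19 ± 1.33 FPKM in cytoplasm (log2 7.77 ± 0.47, adjusted p = 5.3e-08). Rmrp, the RNA of RNase MRP, was 8.28 ± 0.94 higher in nuclei, Terc, the RNA template of telomerase, 8.15 ± 0.83 (listed at 2.63, 0 and 0 FPKM in the cytoplasms), the minor spliceosomal Rnu12 8.06 ± 1.31, and Kcnq1ot1, an imprinted antisense RNA, 4.95 ± 0.39 on the log2 scale. Of 82 small RNA precursors 47 were higher and 8 lower in the nucleus (48 and 8 adjusted over the list alone), with a median of 5.98 (camera adjusted p = 7.1e-24), the single list that stayed called with an estimated correlation (adjusted p = 0.042). Its most abundant member, Scarna2, was at 2030000.0, 1090000.0 and 2170000.0 FPKM in the nuclei and at 16982, 0 and 0 FPKM in the cytoplasms, with 0 as listed. Scarna17, Snora5c and Snora68 were at 7818, 1844 and 2098 FPKM on average in nuclei and listed at 0 in all 3 cytoplasms. Small structured noncoding RNAs counted 8 of 10 higher and 1 lower (8 and 1 adjusted over the list alone; adjusted p = 2.1e-06, and 0.23 with an estimated correlation). The lower member was Rn45s, listed at 0 in all 6 nuclei and at 1879.9, 805 and 332 FPKM in WT cytoplasm. Ribosomal RNA had been depleted from the libraries, so these values do not show where its precursor lay. Of 11 nuclear lncRNAs 9 were higher and 0 lower (9 and 1 adjusted over the list alone, adjusted p = 2.9e-08), among them Airn at 3.37 ± 0.45 and Rian at 2.25 ± 0.49. Of 16 snoRNA host genes 8 were higher and 5 lower (9 and 5 adjusted over the list alone, adjusted p = 0.000297), with Snhg8 at 2.99 ± 0.53, Snhg3 at 2.87 ± 0.72 and Gas5 at 1.98 ± 0.28. With an estimated correlation these 2 lists had adjusted p = 0.13 and 0.18.

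Further genes on the nuclear side in WT were Zfp488 (log2 7.87 ± 0.51), Olfr856-ps1 (7.80 ± 0.42), Vmn1r58 (7.37 ± 0.42), Olfr613 (7.18 ± 0.45), Grk4 (6.99 ± 0.41), Lars2, the mitochondrial leucyl-tRNA synthetase gene (6.71 ± 1.15), 4932411L15 (6.43 ± 0.34), A130077B15Rik (8.06 ± 0.47) and A630089N07Rik (7.81 ± 0.53). Gm and Rik genes counted 452 higher and 391 lower among 1644 (435 and 378 adjusted over the list alone; camera adjusted p = 4.2e-11, and 0.59 with an estimated correlation), with a median of -0.03 and a mean of 0.17. Interferon-stimulated genes had 5 of 20 higher and 5 lower (5 and 5 adjusted over the list alone; adjusted p = 0.0046, and 0.59 with an estimated correlation), with Zbp1, a sensor of Z-form nucleic acids, at 4.14 ± 0.45, Eif2ak2, the kinase PKR, at 3.10 ± 0.45, Mx1 at 2.61 ± 0.34 and Ifitm3 at -1.65 ± 0.65. Of the theca and stroma markers 4 of 5 were higher (4 adjusted over the list alone; adjusted p = 0.0012, and 0.11 with an estimated correlation), with Hsd3b1 at 5.85 ± 1.74 FPKM in nuclei and 0.308 ± 0.127 in cytoplasm. Tnfrsf10b, a death receptor gene of the p53 target list, was 4.79 ± 0.36 higher, and Dux, a 2-cell-stage transcription factor gene, 2.19 ± 0.45.

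On the cytoplasmic side in WT stood mRNAs of the housekeeping and oocyte programmes, measured against a median of all tested genes of -0.90 on the log2 scale. That median was 0.02 after median-of-ratios scaling and -0.22 after quantile normalization, so calls of single mRNAs near it depend on the scaling. Histone mRNAs were lowest in nuclei (median -2.18; 28 of 49 lower and 1 higher, 30 and 1 adjusted over the list alone; camera adjusted p = 0.0092), with Hist1h4h at 14.9 ± 7.75 against 235 ± 89.9 FPKM and Hist1h3f at -3.34 ± 0.39. The proteasome (median -1.86, 41 of 44 lower, 2 higher, 42 and 2 adjusted over the list alone, adjusted p = 1.0e-05, Psmg4 -3.19 ± 0.56, Psmb1 -2.50 ± 0.42) followed. Oxidative phosphorylation had a median of -1.70, with 72 of 83, 73 adjusted over the list alone, lower (adjusted p = 2.2e-06, Ndufa7 -3.15 ± 0.65). Ribosomal proteins had a median of -1.70, with 69 of 85 lower and 1 higher (70 and 1 adjusted over the list alone, adjusted p = 2.3e-06). Among them were Rps26 at -2.92 ± 0.55, Rpl32 at -2.85 ± 0.48, and the other way Rps27 at 2.99 ± 0.66. Maternal-effect genes had a median of -1.64, with 32 of 37, 32 adjusted over the list alone, lower (adjusted p = 3.8e-05; Npm2 -2.20 ± 0.36, Ooep -2.20 ± 0.40, H1foo -2.19 ± 0.42). Of the genes of meiotic arrest and maturation 27 of 34, 28 adjusted over the list alone, were lower (adjusted p = 0.00067), among them Mos, the kinase of egg arrest (-2.10 ± 0.39), Ccnb1 (-2.04 ± 0.41) and Aurkc (-3.22 ± 0.47). Of the list ribosome biogenesis 41 of 68, 41 adjusted over the list alone, were lower (adjusted p = 0.0017). Of the list cytoplasmic RNA decay 32 of 47, 33 adjusted over the list alone, were lower (adjusted p = 0.0072). Of the list PI3K-mTOR growth signalling 28 of 41, 28 adjusted over the list alone, were lower (adjusted p = 0.012). Of the list chromatin modifiers 35 of 52, 36 adjusted over the list alone, were lower (adjusted p = 0.016). Of the list nuclear pore and lamina 31 of 41, 32 adjusted over the list alone, were lower (adjusted p = 0.028). Of the list mRNA export and TREX 21 of 29, 23 adjusted over the list alone, were lower (adjusted p = 0.046). With an estimated correlation the adjusted p of these 12 lists was 0.80 to 0.85, and against the median of all genes cytoplasmic RNA decay, chromatin modifiers and nuclear pore and lamina turned to the nuclear side under quantile normalization.

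The other lists were not called in WT by camera. Fry, which tests a list against no change and not against the other genes, called 26 of 32 lists in WT and 24 in Mtr4-null between compartments (nuclear exosome subunits in WT at adjusted p = 0.0018), where the median of all genes is itself below 0. In the nucleus 0 of 13 nuclear exosome subunits were higher and 9 lower (0 and 10 adjusted over the list alone, camera adjusted p = 0.0896), and 1 of 16 MTR4 partner complexes was higher and 12 lower (1 and 12 adjusted over the list alone, camera adjusted p = 0.052). Of 15 zona pellucida and oocyte-secreted factors, 1 was higher and 7 lower (1 and 7 adjusted over the list alone, camera adjusted p = 0.45). Of 22 oocyte transcription factors, 1 was higher and 15 lower (1 and 15 adjusted over the list alone, camera adjusted p = 0.061). Of 22 genes meiotic prophase and recombination, 3 were higher and 7 lower (3 and 7 adjusted over the list alone, camera adjusted p = 0.81). Of 55 splicing factors, 2 were higher and 30 lower (2 and 30 adjusted over the list alone, camera adjusted p = 0.25). Of 7 2-cell-stage genes, 2 were higher and 3 lower (2 and 3 adjusted over the list alone, camera adjusted p = 0.54). Of 28 p53 targets, 2 were higher and 15 lower (2 and 15 adjusted over the list alone, camera adjusted p = 0.54). Of 32 genes integrated stress response, 2 were higher and 16 lower (2 and 16 adjusted over the list alone, camera adjusted p = 0.64). Of 23 immediate early genes, 0 were higher and 6 lower (0 and 5 adjusted over the list alone, camera adjusted p = 0.895). Of 13 granulosa cell markers, 2 were higher and 7 lower (2 and 7 adjusted over the list alone, camera adjusted p = 0.97). Of 5 blood and endothelial markers, 0 were higher and 1 lower (0 and 1 adjusted over the list alone, camera adjusted p = 0.795). Of 7 antisense and opposite-strand transcripts, 1 was higher and 2 lower (1 and 2 adjusted over the list alone, camera adjusted p = 0.77). No mitochondrially encoded gene was among those tested. Of single oocyte genes, Gdf9 (-1.97 ± 0.46), Bmp15 (-1.68 ± 0.53) and Nobox (-2.36 ± 0.36) were lower in the nucleus, while Zp1 (-0.69 ± 0.54), Zp2 (-0.17 ± 0.56), Zp3 (-0.76 ± 0.50), Kit (-1.10 ± 0.48) and Figla (-0.76 ± 0.34) had no call and were on the nuclear side after median-of-ratios scaling (0.45, 0.97, 0.38, 0.03 and 0.33). Skiv2l2 itself was -1.98 ± 0.57 and the exosome subunit gene Mphosph6 -1.90 ± 0.43. In all, 7509 genes were called between the WT compartments, 1583 higher and 5926 lower in the nucleus. Median-of-ratios scaling called 3787 genes, 2559 higher and 1228 lower, and quantile normalization 3262, 1658 higher and 1604 lower. The balance of higher and lower genes thus depends on the scaling. Both scalings bring the libraries to a similar centre, so they cannot tell what the larger number of lower genes rests on. Of 139 named calls 39 were lost with the first scaling and 40 with the second, among the genes given here Skiv2l2 and Ifitm3 with both, Bmp15 with the first and Mphosph6 with the second. The lists of PI3K-mTOR growth signalling, mRNA export and TREX, and chromatin modifiers lost the call with both scalings. Quantile normalization also ended it for cytoplasmic RNA decay, nuclear pore and lamina, meiotic arrest and maturation, and interferon-stimulated genes.

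**Figure D4:**
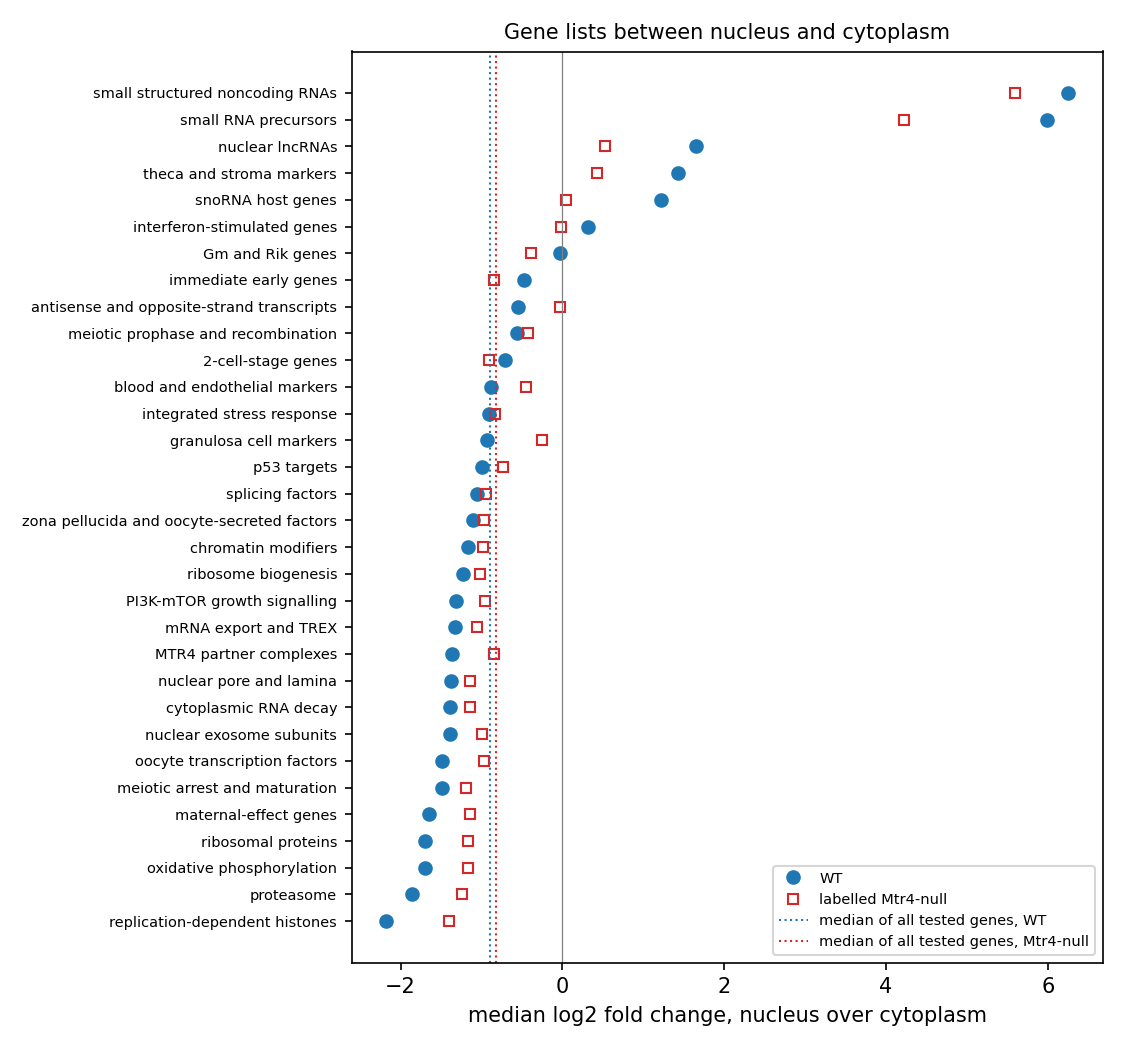
Gene lists between nucleus and cytoplasm. The horizontal axis is the median log2 fold change of each list's tested genes, with filled circles for WT, open squares for the libraries labelled Mtr4-null, and dotted lines for the median of all tested genes (-0.90 and -0.82). Small RNA lists lie far on the nuclear side in both genotypes, and 3 lists that lie left of the dotted line in WT (cytoplasmic RNA decay, chromatin modifiers, nuclear pore and lamina) move right of it under quantile normalization.

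The same comparison in Mtr4-null oocytes, with the library labelled Mtr4-null nucleus replicate 1 among the nuclei, gave a similar order of RNA classes. Rmrp (8.45 ± 0.94), Rpph1, the RNA of RNase P (6.21 ± 0.79), Rprl3 (6.23 ± 1.10), Malat1 (5.84 ± 0.47), Terc (5.02 ± 0.83), Kcnq1ot1 (3.23 ± 0.39), Olfr856-ps1 (4.88 ± 0.42), Zfp488 (4.73 ± 0.51), Vmn1r58 (4.64 ± 0.42), Grk4 (4.54 ± 0.41) and Olfr613 (4.26 ± 0.45) were higher in the nucleus on the log2 scale. Small RNA precursors counted 39 of 82 higher and 5 lower (42 and 5 adjusted over the list alone; camera adjusted p = 5.4e-45, and 0.0052 with an estimated correlation). Nuclear lncRNAs had 2 of 11 higher (2 adjusted over the list alone; adjusted p = 5.6e-06, and 0.22 with an estimated correlation). Lower in the nucleus were Coro2b (-2.72 ± 0.50), Aprt, of purine salvage (-2.67 ± 0.59), Hsd17b10 (-2.78 ± 0.73), Defb8 (-2.99 ± 0.62), Hist1h4d (-2.59 ± 0.58), Gm13103 (-2.76 ± 0.72) and C130074G19Rik (-2.94 ± 0.44). Defb8 was listed at 0, 0 and 8.35 FPKM in the nuclei and Hsd17b10 at 1.40, 0 and 17.3 FPKM. Rn45s was listed at 0 in the 3 nuclei and at 2211, 20429 and 9796 FPKM in the cytoplasms. Of maternal-effect genes 23 of 37, 34 adjusted over the list alone, were lower (camera adjusted p = 0.0012), with Nlrp5 at -1.62 ± 0.52. The numbers were, of ribosomal proteins 47 of 85, 60 adjusted over the list alone (adjusted p = 0.0005, Rps16 -1.77 ± 0.43), and of the proteasome 30 of 44, 38 adjusted over the list alone (adjusted p = 0.000505, Psma6 -1.96 ± 0.53). With an estimated correlation the adjusted p was 0.797 for each of the 3 lists.

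Camera called 17 of 32 lists here and 19 in WT, and with an estimated correlation small RNA precursors alone in each genotype. In all, 4230 genes were called, 537 higher and 3693 lower in the nucleus, where simulated data gave 116, 180 and 87 false calls in 3 runs. Of the calls of WT, 495 were higher and 2955 lower in both genotypes and 13 went opposite ways, while independent lists of these sizes would share 64.6 and 1663. Pearson's r across genes was 0.80, and the 2 comparisons share no library. The count depended on single libraries. It was 332, 588 and 8522 without the nuclei labelled Mtr4-null replicates 1, 2 and 3, 177, 180 and 193 without the Mtr4-null cytoplasms, 346, 312 and 307 without the WT cytoplasms, and in a fit of these 6 libraries alone, which recovered 0% of genes changed by 1 or 2 in simulated data, 111 genes were higher and 12 lower. Scaling by median of ratios called 647 genes, 614 higher and 33 lower, and quantile normalization 487, 409 higher and 78 lower. Of 119 named calls, 84 were lost by the first scaling and 85 by the second, and the median of all genes moved from -0.82 to -0.04 and -0.10. Hsd17b10, Hist1h4d, Gm13103, Nlrp5 and Psma6 lost the call with both scalings, and Aprt and Rps16 under quantile normalization, while the calls named here on the nuclear side held with both.

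For 16 genes the genotype effect differed between nucleus and cytoplasm, 3 with the effect more positive in the nucleus and 13 with it more positive in the cytoplasm. Pnpla3 had a genotype effect of -1.28 in the nucleus and -5.36 in the cytoplasm (difference 4.09 ± 0.62, adjusted p = 0.013), and Hist2h2bb -0.53 and -4.89 (4.37 ± 0.74). In the nuclei labelled Mtr4-null Pnpla3 was at 23.3, 5.33 and 6.12 FPKM, against 30.1, 16.8 and 27.2 in WT nuclei. Hist2h2bb was at 518, 87.8 and 136 FPKM, against 217, 227 and 378. Replicates 2 and 3 thus lay below every WT nucleus for both genes, and replicate 1 did not. For 4930470H14Rik the effects were -0.86 and 4.05 (-4.91 ± 0.55), for E030030I06Rik -0.74 and 3.64 (-4.38 ± 0.61), for Col6a4, a collagen VI chain gene, -0.84 and 1.63 (-2.47 ± 0.44), and for Speer8-ps1 -3.16 and -0.03 (-3.12 ± 0.46). Malat1 had a difference of -1.93 ± 0.66 without a call (adjusted p = 0.29), as had Skiv2l2 with 2.75 ± 0.81 (adjusted p = 0.19). Camera called 10 lists, with nuclear lncRNAs (median -1.37, adjusted p = 3.7e-06), snoRNA host genes (-0.83, 0.0056) and Gm and Rik genes (-0.33, 8.2e-06) toward lower nuclear values in Mtr4-null, and oxidative phosphorylation, the proteasome, ribosomal proteins, maternal-effect genes, histones, meiotic arrest and maturation and ribosome biogenesis toward higher. With an estimated correlation the adjusted p was 0.60 for the first 2 and 0.95 for the other 8. The called members were few, with 7 lower and 0 higher of 1644 Gm and Rik genes (42 and 2 adjusted over the list alone), 1 of 49 histones, 1 higher and 1 lower of 82 small RNA precursors, and 0 elsewhere.

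The libraries labelled Mtr4-null nucleus replicates 1 and 3, both in doubt, enter this test. It called 170, 24 and 289 genes without the nuclei labelled Mtr4-null replicates 1, 2 and 3, 61 without WT nucleus replicate 2, 22 and 15 without WT nucleus replicates 3 and 1, 11, 5 and 6 without WT cytoplasm replicates 1, 2 and 3, and 5, 10 and 9 without the Mtr4-null cytoplasm replicates 1, 2 and 3. All 8 named calls held without each of the nuclei labelled Mtr4-null, and 3 to 5 of the 8 held without a single cytoplasm library. Without WT nucleus replicate 1 Hist2h2bb, Col6a4 and 1810019D21Rik lost the call, and without replicate 3 the last 2. Pnpla3 lost the call under quantile normalization, and Hist2h2bb, Speer8-ps1 and 1810019D21Rik with a pseudocount of 0.1.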

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

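The tests of a swap of libraries and of mRNA retained in nuclei, and the choice of genes without a WT nucleus at a time, told below, were chosen only after the result was seen; the other tests in this part were written before their values were computed. The 16 genes whose genotype effect differed between compartments stand here because the design compares genotypes within each compartment. All of these differences include the library labelled Mtr4-null nucleus replicate 1. The difference (nucleus minus cytoplasm) was 4.09 ± 0.62 for Pnpla3 and 4.37 ± 0.74 for Hist2h2bb, whose levels fell in the cytoplasm and had no call in the nucleus. For both genes the nuclei labelled Mtr4-null replicates 2 and 3 lay below every WT nucleus, and replicate 1 did not. The difference was -4.91 ± 0.55 for 4930470H14Rik, -4.38 ± 0.61 for E030030I06Rik, -2.51 ± 0.43 for 4930405P13Rik, -2.47 ± 0.44 for Col6a4 and -2.85 ± 0.51 for 1810019D21Rik, whose levels were higher in Mtr4-null cytoplasm. It was -3.12 ± 0.46 for Speer8-ps1 and -1.99 ± 0.35 for Igsf9, which were low or at 0 in every library but the WT nuclei. Another 6 genes were listed at 0 in all 3 nuclei labelled Mtr4-null and below 1 FPKM in every cytoplasm, so their differences depend on the added 1 FPKM and are not folds. These were -7.78 for Snora43, with WT nuclei at 174, 141 and 426 FPKM, -3.45 for 1600014K23Rik (11.2, 11.2 and 4.83), -2.45 for 1700020G17Rik (4.12, 5.00 and 4.32), -2.82 for 1700026L06Rik (3.58, 6.52 and 3.76), -2.18 for Kncn (3.92, 4.08 and 2.94) and -2.08 for Ltb4r2 (3.05, 2.47 and 4.62). Likewise Mir365-2 (difference 4.62) was at 24.3, 15.6 and 34.4 FPKM in WT cytoplasm and listed at 0 in the other 3 groups. Of 100 ways to regroup genotypes within compartments, 6, the real one included, called at least 16 genes, and the highest of the others called 689. The draw allowed regroupings that keep or reverse the true split of a single compartment, so that a genotype effect can enter their counts. The test therefore cannot tell whether a count of 16 would arise without a genotype effect.

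The library labelled Mtr4-null nucleus replicate 1 holds Skiv2l2 at 7.98 FPKM. Over the 3050 genes called between the cytoplasms alone, its mean log2 difference from the WT nuclei, signed by the cytoplasmic change, was -0.0868, against -0.0702, 0.00311 and 0.0671 in the WT nuclei and 0.570 and 0.605 in the other nuclei of its label. The range of the WT nuclei had been set as the bound for a WT library or for oocytes that kept the gene. The value falls just outside it, on the side away from Mtr4-null, so by that bound the test is undecided. It does show that this library lacked the shift seen in the other nuclei of its label. A swap with a WT nucleus library is not seen, since the highest shift of those is 0.0671, nor is RNA of granulosa cells, since the summed FPKM of 28 markers was 110.1 against 79.0 to 120 in the WT nuclei. The values could still come from oocytes that kept the gene. Genes higher in WT nuclei were also chosen without WT nucleus replicate 1, 2 or 3 in turn. Over them this library had medians of -0.618, -0.867 and -0.639, against 0.169, -0.661 and 0.249 in the WT nucleus left out. It lay below that WT nucleus each time, and closest to it for WT nucleus replicate 2. The WT nuclei left out also differ from each other, so these values do not settle the label.

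The library labelled Mtr4-null nucleus replicate 3 lies near the cytoplasms. The share of Mtr4-null cytoplasm that would place each gene between WT nuclei and Mtr4-null cytoplasm was taken as a median per list. It was 0.630 for 64 ribosomal protein genes, 0.624 for 72 genes of oxidative phosphorylation and 0.620 for 29 maternal-effect genes. The ratio of largest to smallest was 1.02, as cytoplasm carried over into the nucleus sample would give. These lists also have similar medians between WT compartments (-1.70, -1.70 and -1.64), so any common rise of mRNAs would give similar shares. The ratio therefore does not single out carry-over. Retention of mRNA in nuclei without MTR4 might also show in replicate 2. Its median difference from the WT nuclei over 5926 genes higher in WT cytoplasm was -0.297, within the WT range of -0.396 to 0.230. With genes chosen without a WT nucleus at a time it was -0.252 to -0.134, and the WT nuclei left out were at -0.313 to 0.302. Over genes higher in WT nuclei, chosen the same way, replicate 2 was at -1.33 to -1.09. Such genes thus fell further in it than those higher in WT cytoplasm. FPKM is a share of a library, so this test cannot set retention aside. A common scaling of all genes would raise the 1536 genes higher in WT nuclei too, and their median in replicate 3 was -0.790, and -0.976 to -0.804 with genes chosen without a WT nucleus at a time. Without replicate 3, 5 of the 7 lists called between the nuclei kept the call, and ribosomal proteins and Gm and Rik genes lost it.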

How the results depend on the processing

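Counts of genes depended on the fit. Most single results kept their direction, but many alternatives cannot change a sign. The replicate block, fits of only the 2 groups compared and variances without a trend leave fold changes as they are. So does leaving out a library outside the 2 groups compared. Many named genes were also chosen for their large changes. The numbers of kept results therefore do not measure how stable directions are. Outside the omission of single libraries, 3280 comparisons of a named gene with an alternative kept direction and side of the threshold, 733 lost the call, 40 gained it and 28 changed sign. For lists 521 were kept, 139 lost the call and 3 changed sign. Leaving out single libraries kept 3522 gene results and 614 list results, lost 962 and 22, gained 11 and 0, and turned the sign of 29 and 0. Of the named calls, 15 of 30 in the cytoplasm, 2 of 38 in the nucleus, 88 of 139 between WT compartments, 14 of 119 between Mtr4-null compartments and 3 of 8 in the interaction held in every alternative in which they were tested. The filter at 5 FPKM left all 30, 31, 128, 113 and 7 of them to be tested. Some fits of only 2 groups hold the nuclei labelled Mtr4-null. The spread simulated was that of all 3 of these nuclei, also for fits without replicate 1. In simulated data such fits recovered 0% to 2% of genes changed by 1 or 2 on the log2 scale. A call lost there thus does not tell a changed gene from an unchanged one. Without these fits 7 of 38 in the nucleus and 25 of 119 between Mtr4-null compartments held. The fits that remain take in the smaller spread of the cytoplasms. With all libraries the fit of 4 groups gave 213 to 287 false calls between the nuclei in simulated data. Holding in them is therefore weak support for a change between the nuclei. The fall of Skiv2l2 in the cytoplasm held in every alternative. Where no reason is given, the cause was not tested. The relative depth of the nuclei was low, 0.129 to 0.398 (0.440 by the other reference for the library labelled Mtr4-null nucleus replicate 1), which limits genes of low level. A threshold of 1 on the log2 scale left 1467 higher and 5540 lower genes between WT compartments and 493 and 3290 between Mtr4-null compartments, and all calls of the other comparisons.

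The 298 calls in the nucleus became 102 with a pseudocount of 0.1, 599 without a filter, 26 at 5 FPKM (fewer genes tested), 1271 with median-of-ratios scaling (342 higher, 929 lower), 1140 with quantile normalization. They became 5 in the fit of only 2 groups, 153 with library weights, 3966 without the nuclei labelled Mtr4-null replicates 1 and 3, 50 in the fit of 2 groups without replicate 1, and 125 to 1347 on leaving out single libraries. The 248 in the cytoplasm became 140, 139 and 147 with the first 3, 104 with quantile normalization (55 higher, 49 lower), and 3050 in the fit of only 2 groups. They became 4802 with library weights, 1371 without both doubtful nuclei, and 56 to 614 on leaving out single libraries. Between WT compartments 7509 became 3787 with median-of-ratios scaling, 3262 with quantile normalization and 5724 to 8607 on leaving out single libraries. Between Mtr4-null compartments 4230 became 1201 without a filter, 647 and 487 under the 2 scalings, 1.2e+02 in the fit of only 2 groups (111 higher, 12 lower), and 98 in that fit without replicate 1. They became 8342 with library weights, 8471 without both doubtful nuclei, and 177 to 8522 on leaving out single libraries. The 16 of the interaction became 111 without a filter, 187 (14 higher, 173 lower) and 76 (13 higher, 63 lower) under the 2 scalings, 961 with library weights, 1450 without both doubtful nuclei, and 5 to 289 on leaving out single libraries.

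With the replicate number as a block the counts were 377, 328, 7809, 4970 and 69 in the order above. The source does not say whether the numbers pair the libraries. Deviations of libraries with the same number correlated at -0.15 to 0.30, with 0.058, 0.303 and 0.117 between Mtr4-null nucleus and cytoplasm, so pairing stays open.

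For Skiv2l2 the nuclear log2 fold change was 0.089 with library weights and -2.19 without both doubtful nuclei. On leaving out single libraries it was -1.76 to -0.30, the lowest without the library labelled Mtr4-null nucleus replicate 1. Between Mtr4-null compartments the log2 fold change of Skiv2l2 was 0.77, but -0.49 without both doubtful nuclei. It was -0.068 without the library labelled Mtr4-null nucleus replicate 1 in either fit, and up to 1.39 on leaving out single libraries.

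Genes without a call changed sign as follows. In the nucleus, Zp1 (0.10) and Zp2 (0.21) did under quantile normalization, Figla (-0.081) with library weights, and Gdf9 (-0.23), Zp3 (-0.51) and Nobox (-0.28) without both doubtful nuclei. On leaving out single libraries the nuclear ranges were -0.77 to 0.53 for Bmp15, -0.58 to 0.53 for Zp1, -0.60 to 0.46 for Zp2, -0.15 to 0.64 for Zp3 and -0.78 to 0.39 for Kit. In the cytoplasm, Gdf9 (-0.94), Kit (0.12) and Gas5 (-0.070) did under quantile normalization, Gdf9 (-0.013) and Kit (0.12) with library weights, and the ranges were -0.022 to 0.035 for Gdf9, -0.094 to 0.51 for Zp1, -0.23 to 0.23 for Kit and -0.056 to 0.12 for Gas5. Between WT compartments, Zp1 (0.45), Zp2 (0.97), Zp3 (0.38), Kit (0.032) and Figla (0.33) did with median-of-ratios scaling, Kit (0.26) and Figla (0.38) under quantile normalization, as did the called Slc7a6os (0.10), and Zp2 (0.021) with library weights, with a range of -0.45 to 0.17. Between Mtr4-null compartments Zp2 was at 0.0015 with median-of-ratios scaling. In the interaction, Zp3 (0.043) did under quantile normalization, Gdf9 (-0.23), Bmp15 (-1.17) and Figla (0.23) without both doubtful nuclei, and the ranges were -0.21 to 1.09 for Bmp15, -0.77 to 0.33 for Zp1, -0.62 to 0.17 for Zp3, -0.74 to 0.44 for Kit and -0.45 to 0.16 for Figla.

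By the direction of the list test, those that turned were chromatin modifiers between WT compartments (adjusted p = 0.95 under quantile normalization), Gm and Rik genes in the nucleus (0.89 without both doubtful nuclei) and between Mtr4-null compartments (0.41 with fry). The difference in the share of the 100 most abundant genes, Mtr4-null minus WT, ranged from -8.50 to 0.58 points in the nucleus and from -1.46 to 4.90 in the cytoplasm on leaving out single libraries, the sign turning without the library labelled Mtr4-null nucleus replicate 3 and without Mtr4-null cytoplasm replicate 2. Medians lay on the same side of the median of all genes under all 3 scalings for 23 of 32 lists in the nucleus, 28 in the cytoplasm, 20 between WT compartments, 21 between Mtr4-null compartments and 26 in the interaction. By this measure cytoplasmic RNA decay and nuclear pore and lamina also turned between WT compartments under quantile normalization.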

Other observations

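In this part the tests of strain background and of single libraries, and the count of genes nearer to a genotype, were chosen only after the result was seen. Several genes of the major histocompatibility region changed in the cytoplasm, outside the naming rule. H2-Aa, a class II antigen gene, was at 35.0, 28.8 and 31.5 FPKM in WT and 1.65, 3.07 and 1.38 FPKM in Mtr4-null cytoplasm (log2 -3.47 ± 0.38, adjusted p = 0.00039). H2-K1, a class I gene, was at 4.84, 6.66 and 6.21 FPKM in WT and 28.7, 41.3 and 42.6 FPKM in Mtr4-null (log2 2.47 ± 0.50, adjusted p = 0.021). The nuclei labelled Mtr4-null replicates 2 and 3 held 27.8 and 41.4 FPKM of H2-K1, and the library labelled Mtr4-null nucleus replicate 1 6.18, against 5.22, 6.69 and 4.26 in the WT nuclei. H2-T23 (log2 2.30 ± 0.46) and Mog, a myelin protein gene (2.69 ± 0.35), rose and Trim15 (-2.91 ± 0.62) fell. H2-K1 and H2-Aa have many alleles between mouse strains, and reads of an allele unlike the reference can be lost in mapping. Whether this occurred here was not tested.

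Many cytoplasmic calls go from near 0 in a single genotype to clear expression in the other, which a difference in strain background could give. If such a difference lay in few regions, the 141 genes called with a log2 change of at least 2 would lie together along the genome. A difference spread over the whole genome need not place them together, so their positions cannot speak to it. The most loaded run of 100 consecutive tested genes, with calls within 5 genes counted once, held 6 of 125 runs of calls, against a median of 5 and a 95% point of 6 in 10000 random placements (permutation p = 0.090), and this run is the one with H2-K1, H2-Aa, H2-T23, Trim15 and Mog. The test leaves a strain difference open. The share of these genes whose libraries overlap between genotypes was 0%, which says nothing about single bad libraries, because calls of this size leave no room for overlap.

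Other groupings of the same 6 libraries were counted for each comparison, with 10 ways to split them, too few for a share under 0.05. In the cytoplasm 1 of 10 splits, the real one alone, called at least 248 genes, and the highest other called 1. Between compartments it was 1 of 10 in WT (highest other 1) and 1 of 10 in Mtr4-null (highest other 2). In the nucleus 2 of 10 called at least 298, the second with 426 genes, and that split set WT nucleus replicates 1 and 3 and the library labelled Mtr4-null nucleus replicate 3 against the rest. Its first 3 libraries had relative depths of 0.174, 0.166 and 0.398 and the others 0.143, 0.147 (0.440 by the other reference, for the library labelled Mtr4-null nucleus replicate 1) and 0.129.

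The genotype effects of the nucleus and the cytoplasm, which share no library, had 9 genes higher and 5 lower in both and 0 opposite, where independent lists of these sizes would share 0.796 and 1.64 (Pearson's r across genes 0.31). Without the library labelled Mtr4-null nucleus replicate 1 the numbers were 148, 78 and 0, where independent lists would share 15.8 and 10.1 (r = 0.41). If the library labelled Mtr4-null nucleus replicate 3 held carried-over cytoplasm, which is not settled, this overlap would rise by itself, and the numbers for independent lists would not be those for no shared change. Of the 141 genes, the library labelled Mtr4-null nucleus replicate 1 was nearer to Mtr4-null than to WT cytoplasm for 38, the WT nuclei for 38, 47 and 40, and the other nuclei labelled Mtr4-null for 100 and 131.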
